A study of Mus musculus with 2 samples.

How the data were processed

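Single-cell RNA sequencing (10x Genomics 3' libraries) was available for viable CD45+ cells sorted from MC38 tumours, a mouse colon carcinoma line, grown in C57BL/6J mice. Per the labels' protocols, tumour cells were placed intradermally at 4 sites per mouse and left for 7 days, tumours were injected with a control or with an antibody against PD-1 at 200 µg per mouse per day, and tumours were taken on day 10. There were 2 libraries, 1 control and 1 anti-PD-1. The number of mice behind each library is not given in the sources used here. With 1 library per group no test across samples can be made, and no p-value, standard error or count of changed genes is given.

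The deposited values were UMI counts per gene and barcode, not normalised, for 27998 genes and 737280 barcodes in each matrix. Per the submitters' processing notes, the authors used Cell Ranger 2.1 with the mm10 build. The matrices list barcodes without cells as well as cells, so cells were called anew. A barcode was called a cell when its UMI total reached 1/10 of the 0.99 quantile of the 3000 deepest barcodes, the rule of that Cell Ranger generation. This gave a minimum of 1132.51 UMIs in the control library and 1432.18 in the anti-PD-1 library. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as built into scanpy, at its automatic threshold, which marked 0 control and 4 anti-PD-1 cells. The doublet caller therefore removed almost nothing, and cells holding transcripts of 2 types remain in the data.

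The libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15, using 2000 variable genes, 30 principal components, 15 neighbours and resolution 1.0. Arg1, the interferon, cell cycle and dissociation lists, mitochondrial and ribosomal protein genes, Xist and Y-linked genes were left out of the clustering. Clusters were named from marker genes fixed before the data were examined, and a name ending in "-like" means no more than that. A cluster stayed unnamed when its markers' mean log2 ratio to all other cells was at most 0.5, when fewer than 3 markers were over 2-fold, when none was among its 10 leading genes, or when another class had more markers there. Monocyte/macrophage-like cells were clustered again at resolution 0.5 into 8 subclusters.

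UMIs were summed over the cells of a class and library and divided by the class total, giving CPM. Ratios are anti-PD-1 over control on the log2 scale, with a 95% conditional binomial interval. Levels carry exact Poisson intervals, shares of cells exact binomial (Clopper-Pearson) intervals, and ratios of shares a log-normal approximation. For a count of 0, the upper limit given is that of 3 counts, not the exact bound. All of these cover counting error only, not differences between animals or variation from cell to cell. A gene under 3 UMIs in the lower library was set to 3 UMIs there for ranking and for list medians, and against 0 UMIs its ratio is a bound. Ratios were formed in classes with at least 50 cells in both libraries, which were monocyte/macrophage-like, regulatory T-cell-like, NK-cell-like, cDC2-like and all T-cell-like cells together. Because different clusters can hold most of a class in each library, a cluster-matched ratio was also formed, in which the CPM of each cluster with at least 10 cells in both libraries were averaged with the same weights. Its interval treats the averaged CPM as counts over the total of those clusters, so it is too narrow where a cluster holds few cells.

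For gene lists, 22 lists were fixed before the data were examined. The median log2 ratio of members with at least 20 UMIs was set beside 10000 random lists of the same size matched on mean expression. A list is called higher or lower when its median lay outside the central 95% of the random medians, which describes these libraries and is not a test between conditions. Genes named in the text followed a rule of size, also fixed beforehand. It took the 12 highest and 12 lowest ratios in monocyte/macrophage-like and in all T-cell-like cells, and the 4 highest and 4 lowest in other classes, among genes with at least 50 UMIs and 50 CPM in the library where they were higher. Mitochondrial, ribosomal, immunoglobulin and T-cell receptor segment genes and unnamed gene models were left out. For Arg1-positive against Arg1-negative cells, it took 12 genes in each direction that went the same way in both libraries, ranked by the smaller ratio, with at least 50 UMIs and 50 CPM in the higher cells of each library. Arg1, Pdcd1, Cd274, Ifng, Gzmb, Cxcl9, Nos2, Mrc1 and Spp1 were looked at in every comparison, as were up to 4 members of each list.

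Free RNA was read from barcodes with 10 to 50 UMIs. Its share in cells, estimated from the macrophage genes C1qa, C1qb, C1qc, Apoe, Ms4a7 and Lyz2 in NK- and T-cell-like cells, was 1.76% in the control and 2.04% in the anti-PD-1 library. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, and the Arg1 split after thinning to 2000 UMIs. Gene positions are from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names.

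The ratio and list steps were tested on simulated data of 27998 genes, in 20 simulations per class with 200 changed genes. Changed genes and list members were drawn only from genes with at least 50 expected UMIs in the library with the smaller class total, and intervals were checked only for those. For the comparison in monocyte/macrophage-like cells these were 3523 genes. Intervals held the true value for 95.7% of them, and 99.6% of genes changed 2-fold and 100% of those changed 4-fold had an interval excluding no change. Genes with fewer UMIs, which enter the lists from 20 UMIs, were not checked. The simulated class totals were drawn from the model that the intervals assume, with no variation between cells or subclusters. The simulations therefore check the computation only, and the intervals are too narrow where cells of a class vary. Alternatives chosen before the data were examined were shared UMI minimums, mitochondrial limits of 5% and 20%, no doublet removal, resolutions 0.5 and 2.0, clustering with the left-out genes, median-ratio scaling, equal weight per cell, thinning, free-RNA subtraction, other UMI minimums for genes, and other forms of the Arg1 split. Alternatives added after seeing the data were a 500-UMI minimum, removal of the highest Scrublet scores, cluster matching, cluster matching without each cluster under 20 cells in a library, leaving out subclusters 6 and 8, a 50-UMI minimum for list members, and leaving Arg1 out of the lists in the Arg1 split.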

Results

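The series profiled viable CD45+ (immune) cells from MC38 tumours by droplet single-cell RNA sequencing, with 1 library from control-injected and 1 from anti-PD-1-injected tumours. Its title concerns Arg1, which encodes the arginine-degrading enzyme arginase 1, as a marker of suppressive infiltrating cells. The control matrix held 5203415 UMIs and the anti-PD-1 matrix 13717817. After calling and filtering, 1147 control cells and 2927 anti-PD-1 cells were retained, with medians of 3327 and 3024 UMIs and of 1213 and 1141 genes per cell. There were no replicates, so every interval below covers counting error only and every difference is between these 2 libraries, with no replicate check.

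The first comparison asked which cell classes made up the sorted cells with and without anti-PD-1. T-cell-like cells made up 21.0% of control cells (95% interval 18.7 to 23.5) and 43.8% of anti-PD-1 cells (42.0 to 45.6). Most of this lay in CD8 T-cell-like cells, which were 2.53% (1.70 to 3.61) of control and 24.3% (22.7 to 25.9) of anti-PD-1 cells, a ratio of 9.59 (6.66 to 13.8). Regulatory T-cell-like cells made up a smaller share, 14.0% and 10.0% of cells (ratio 0.711, 0.594 to 0.851), and CD4 T-cell-like cells were at 2.79% and 3.48% (ratio 1.25, 0.845 to 1.85). Shares are parts of a whole, so the larger CD8 T-cell-like share lowers those of other classes by itself. A lower share here or below therefore does not show a loss of cells. A further T-cell-like cluster led by Gzmm and Cd8b1 held 1.66% and 6.08% of cells.

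NK-cell-like cells were 30.3% of control and 18.2% of anti-PD-1 cells (ratio 0.603, 0.537 to 0.678). Monocyte/macrophage-like cells were 28.8% and 17.3% (ratio 0.601, 0.533 to 0.678), and cDC2-like cells, a conventional dendritic cell class, 6.02% and 2.80% (ratio 0.466, 0.341 to 0.637). Migratory-DC-like cells were at 2.79% and 3.28% (ratio 1.18, 0.793 to 1.74). Neutrophil-like cells were 0.959% and 5.53% (ratio 5.77, 3.15 to 10.6). B-cell-like cells were 8 of 1147 and 6 of 2927. Unnamed clusters held 9.50% and 8.85% of cells.

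Counting cells by transcripts alone gave the same direction for CD8 cells, with a smaller ratio than that of the class. The class does not hold all such cells. Cd8a was also at 598 CPM in the Gzmm- and Cd8b1-led cluster and at 448 CPM in an unnamed cluster led by Rrm2 and Ube2c. With each cell thinned to 1000 UMIs, 5.14% (3.94 to 6.59) of control and 30.7% (29.1 to 32.5) of anti-PD-1 cells carried a Cd8 and a Cd3 UMI, and 7.41% and 37.2% did without thinning. In monocyte/macrophage-like cells, which should lack them, these were 0 of 330 cells, which allows a share of up to 0.909%, and 2 of 506, at median depths of 4439.5 and 5168.5 UMIs. Cells with C1q and macrophage transcripts were 16.0% of control and 6.59% of anti-PD-1 cells, and 22.1% and 10.2% without thinning. Shares are of CD45-sorted cells above a UMI minimum of 1132.51 in control and 1432.18 in anti-PD-1, and the neutrophil-like ratio was 2.86 with a 500-UMI minimum and 19.8 with the higher minimum in both libraries. Within the CD8 T-cell-like class, a cluster led by Ifng and Ccl3 held 20 of 29 control cells, whereas a cluster led by Gzmk held 611 of 710 anti-PD-1 cells.

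**Figure D1:**
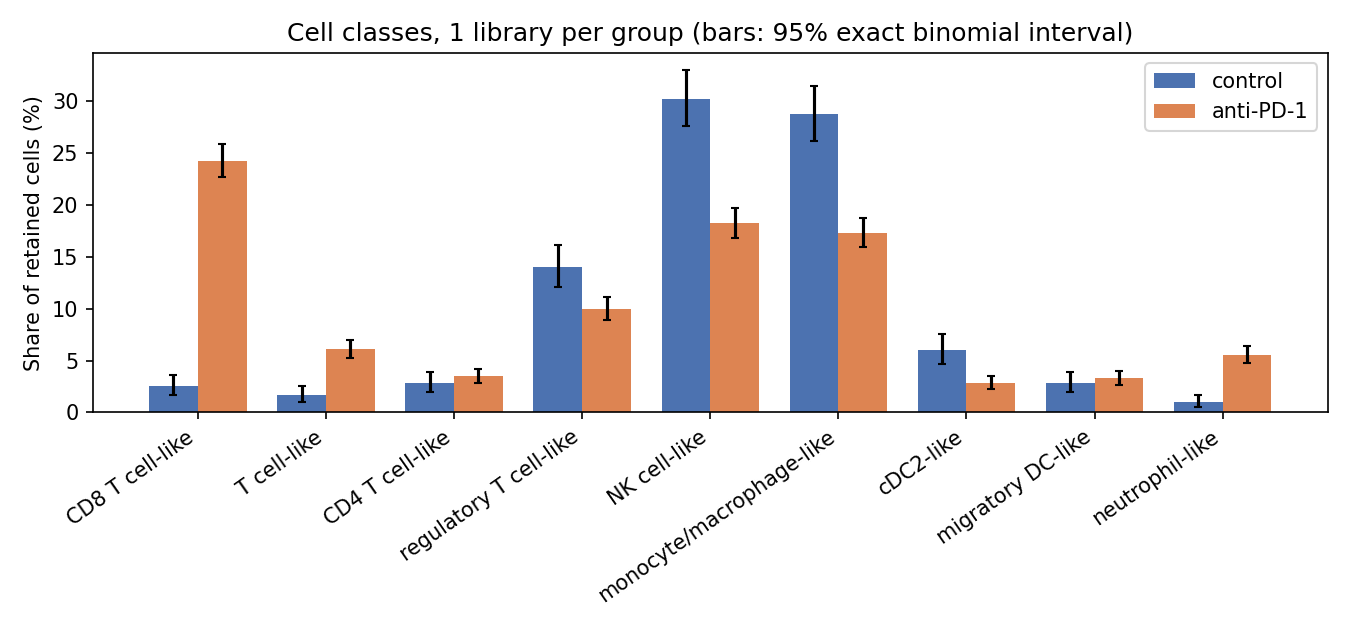
Share of retained cells (%) in each cell class for the control and the anti-PD-1 library, 1 library each; error bars are 95% exact binomial intervals. CD8 T-cell-like cells stand at 2.53% and 24.3%, and monocyte/macrophage-like cells at 28.8% and 17.3%.

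The next comparison asked which cells carried Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand, GRCm38). Monocyte/macrophage-like cells held 98.7% of the Arg1 UMIs of control cells and 97.3% of those of anti-PD-1 cells. Their Arg1 level was 2405 CPM (2331 to 2480) in control and 749 CPM (719 to 780) in anti-PD-1, a log2 ratio of -1.68 (-1.76 to -1.61). At 1000 UMIs per cell, 43.3% (37.9 to 48.9) of them carried an Arg1 UMI in control and 17.0% (13.8 to 20.6) in anti-PD-1, and 53.3% and 25.7% without thinning. All T-cell-like cells, which served as background at median depths of 2946 and 2742 UMIs, gave 2.07% and 0.702%, and 20.8 and 9.33 CPM. No Arg1 UMI was found in 162 anti-PD-1 neutrophil-like cells, which allows up to 6.79 CPM.

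Within the class, Arg1 was uneven. Subcluster 7, led by Mt2, Hilpda and Hmox1, reached 6509 CPM (6172 to 6860) in 44 control cells and 6078 CPM (5373 to 6849) in 11 anti-PD-1 cells. The C1qa- and Ms4a7-led subcluster 1 had 2109 and 2787 CPM. The Ccl8- and Mrc1-led subcluster 3 had 1829 CPM (1710 to 1954) in 109 control cells and 310 CPM (241 to 393) in 46 anti-PD-1 cells, where 31.2% (22.7 to 40.8) and 21.7% (10.9 to 36.4) carried an Arg1 UMI at 1000 UMIs per cell, 34 and 10 cells. Subcluster 4, led by Slpi, had 3753 CPM in only 12 control cells and 131 CPM in 75 anti-PD-1 cells. The monocyte-type subclusters 2, led by Ace and Treml4, and 5, led by Hp and Ifitm6, had no Arg1 UMI in control, which allows up to 46.8 and 19.5 CPM, and 2.85 and 0 CPM in anti-PD-1, the latter allowing up to 22.6 CPM.

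The mixture of subclusters differed between the libraries. Most control cells of the class lay in subclusters 3 (33.0%) and 1 (29.1%), and most anti-PD-1 cells in 2 (29.2%) and 1 (21.9%). Subcluster 7 made up 13.3% of the class in control and 2.17% in anti-PD-1. When subclusters were weighted alike in both libraries, the Arg1 log2 ratio was -0.51 (-0.58 to -0.44), and it was -0.17 (-0.25 to -0.10) without subcluster 4 and its 12 control cells and -0.69 (-0.78 to -0.60) without subcluster 7 and its 11 anti-PD-1 cells. These matched values leave out subclusters 6 and 8, without which the unmatched class ratio was -1.34. When the cells were clustered at resolution 2.0 the class ratio was -0.49. The Arg1 ratios of subclusters 1, 4 and 7 changed sign under some alternatives, whereas that of subcluster 3 did not in any alternative that gave a value. Where cells were called or clustered anew, subclusters were found anew. Each took the number of the main subcluster that most of its shared cells came from, so it can hold other cells. Subclusters 1 and 4 changed sign only in such alternatives. In the same cells thinned to 1000 UMIs their ratios were 0.52 and -4.31, against 0.40 and -4.84 in the main setting.

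**Figure D2:**
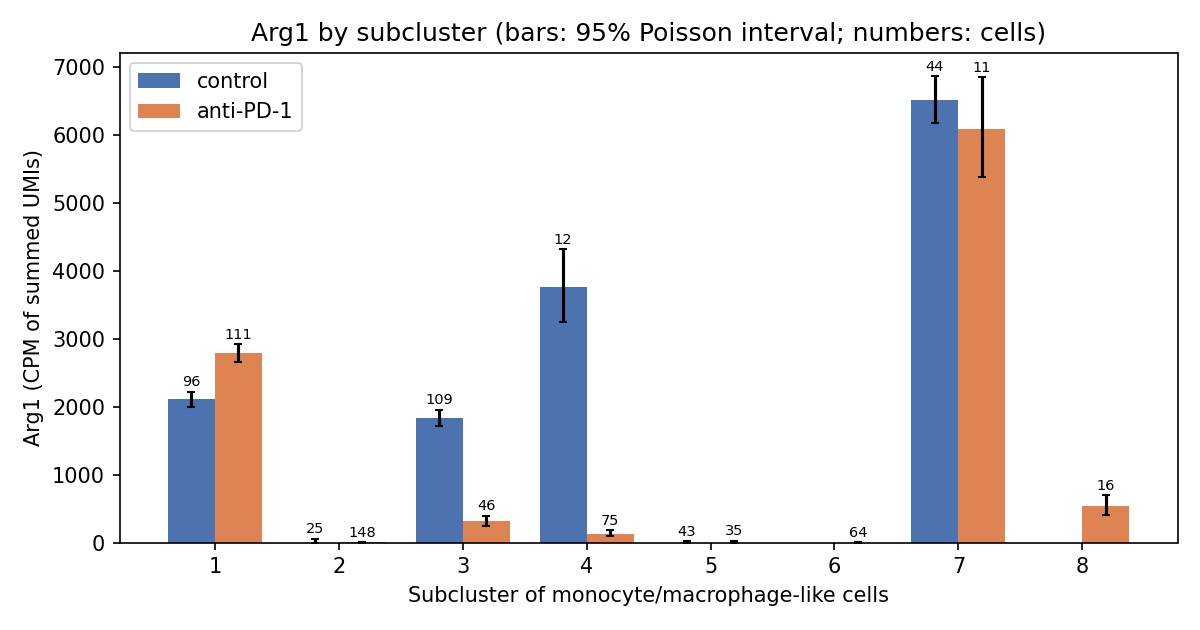
Arg1 level (CPM of summed UMIs) in the subclusters of monocyte/macrophage-like cells, control and anti-PD-1; error bars are 95% Poisson intervals, numbers above bars are cells, and groups under 10 cells are not drawn. Subcluster 7 is the highest in both libraries at 6509 and 6078 CPM.

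The difference between the anti-PD-1 and the control library within monocyte/macrophage-like cells was examined next, where subclusters 3 and 1 hold most control and 2 and 1 most anti-PD-1 cells. Genes of antigen presentation on MHC class II were lower, with 10 of 11 members down and a median log2 ratio of -1.71. Genes of alternative, IL-4-type activation were lower (10 of 12, median -1.39), among them the mannose receptor Mrc1 (136 against 28.0 CPM, log2 -2.28), the lectin Mgl2 (-4.30) and the chemokine Ccl24 (-2.47). Complement and tissue macrophage genes (13 of 14, median -1.11) and hypoxia and glycolysis genes (22 of 23, median -0.90) were lower as well. All 25 measured cell cycle genes were higher (median 1.12), including Birc5 (1.83) and Ccnb2 (1.84), and so were monocyte genes (9 of 12, median 0.82), though not with subclusters weighted alike (0.056, within the random range).

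Interferon response genes were higher by a smaller amount (23 of 36, median 0.25), with the chemokine Cxcl10 at 288 and 1075 CPM (log2 1.90, 1.76 to 2.04). Suppressive factors (-0.60), chemokines (-0.52), lipid and phagolysosomal genes (-0.43) and dissociation genes (-0.70) were lower than random lists. Cytotoxic effector genes (0.54) and regulatory T-cell genes (1.31), which belong to lymphocytes, were higher, and a subcluster led by Gzma and Cd3g held 1 control and 16 anti-PD-1 cells of the class. The arginine and polyamine list (0.06), inflammatory activation (0.26), MHC class I (0.07), inhibitory receptors (-0.15), naive T-cell genes (-0.12), neutrophil genes (0.25) and tumour epithelial genes (0.77) lay within the random range, and the erythrocyte and stromal lists had 1 measured member each.

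With subclusters weighted alike, MHC class II (-0.54), alternative activation (-0.54), complement (-0.25), hypoxia (-0.18) and dissociation genes (-0.47) lay below random lists, and cell cycle (0.87), interferon (0.37) and regulatory T-cell genes (1.30) above them. Suppressive factors (-0.04), chemokines (0.093) and cytotoxic genes (0.20) came to lie within the random range, lipid genes turned higher (0.20), and inflammatory activation (0.48), neutrophil genes (0.35) and inhibitory receptors (-0.50) came to lie outside it. The subclusters went different ways. Complement genes lay above random lists in subcluster 2 (8 of 12 members higher, median 0.32) but below them in subclusters 1, 4 and 7. Interferon genes lay below random lists in subcluster 3 (19 of 31 lower, median -0.15) but above them in subclusters 1, 2, 5 and 7. In subcluster 1, hypoxia genes were higher in 18 of 21 members (median 0.27) and cell cycle genes in 10 of 21 (-0.036, within the random range), and in subcluster 5 MHC class II genes were higher in 8 of 8 (1.07). Cell cycle genes lay above random lists in subcluster 2 (0.30) and in no other subcluster compared. Subcluster 2 had 25 control cells at a median depth of 2398 UMIs and 148 anti-PD-1 cells at 6737.5. Its control cells summed to 64149 UMIs, so the floor of 3 UMIs stood at 46.8 CPM there, and control C1qa, at 15.6 CPM, lay below it. Its list medians therefore rest on few control counts, and it was not left out of the matching in turn. Without subcluster 4, the matched medians were -0.020 for hypoxia, within the random range, and 0.70 for cytotoxic genes, above it. At resolution 2.0 the cell cycle median of the class was -0.031.

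By size, the lowest ratios were Mgl2, Ccl8 (-4.02), Ltc4s (-3.08), Fcrls (-2.73), Ccl24, Mrc1, Tmem119 (-2.14), H2-DMb2 (-2.11), Egr2 (-2.10), Apoe (-2.05), Tmem37 (-1.89) and Tmem176b (-1.89). The highest were Wfdc21 (3 against 314 UMIs, interval 4.27 to 8.11), Lcn2 (0 against 233 UMIs, a log2 ratio of at least 5.40), S100a8 (4.84), S100a9 (2.75), Fpr2 (2.24), Cdc42ep2 (2.23), Trem3 (2.08), Upp1 (2.06), Cxcl10, Ccnb2, Birc5 and Dut (1.79). Lcn2 encodes a neutrophil granule protein, and S100a8 and S100a9 encode calprotectin, an abundant cytosolic protein of neutrophils. A subcluster led by these genes with Elane held 64 anti-PD-1 cells and no control cell. With subclusters weighted alike, the 12 lowest genes stayed below 0 but lay between -2.82 (Ccl8) and -0.37 (Ccl24, at -1.14 without subcluster 7), with Mgl2 at -2.44, Apoe at -1.16 and Mrc1 at -0.96. Among the highest, S100a8 was then at 2.33, Fpr2 at 1.25, Cxcl10 at 1.14 (2.00 without subcluster 4), S100a9 at 0.35 and Trem3 at 0.19, Wfdc21 had an interval of 0.38 to 5.26, Lcn2 a ratio of at least 1.53, and Cdc42ep2 was at 0.25, or at -0.0080 without subcluster 4. S100a8 and S100a9 turned to -0.265 and -1.375 at resolution 2.0. Cxcl9 (0.75), Cd274, which encodes PD-L1 (0.44), Nos2 (1.56) and Spp1 (0.36) were higher in anti-PD-1, and Spp1 was at -0.094 in thinned cells. With subclusters weighted alike Cxcl9 was at 1.46, Cd274 at 0.89 and Spp1 at 0.97.

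In all T-cell-like cells together, most control cells were regulatory T-cell-like and most anti-PD-1 cells CD8 T-cell-like. Cytotoxic effector genes were higher (17 of 22, median 1.004), with the granzymes Gzma (log2 3.30) and Gzmk (2.76), and Ifng, the type II interferon, was at 275 and 558 CPM (1.02, 0.82 to 1.23). Regulatory T-cell genes were lower in 15 of 15 (median -1.39), including Il10 (-1.84). With clusters matched, which left out the Gzmk-led cluster for having 9 control cells, Ifng was at 0.96 and the cytotoxic list at 0.30, the regulatory list was at -0.02, and Gzmb went from -0.51 to 0.073 (-0.043 without the Gzmm-led cluster and its 19 control cells). Pdcd1, which encodes PD-1, was at 186 and 194 CPM (0.06, -0.20 to 0.33).

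Hypoxia and glycolysis genes were lower in 21 of 21 members (median -0.86, cluster-matched -0.52). The other lists lower than random lists were suppressive factors (-0.52), alternative activation (-0.74), MHC class II (-0.79), complement genes (-0.79) and dissociation genes (-0.51), and those higher were inflammatory activation (0.35), naive T-cell genes (0.39) and neutrophil genes (1.13). The alternative activation list, with 4 measured members, and the neutrophil list, with 7, hold myeloid genes and gave no value after subtraction of free RNA, in thinned cells or with members of at least 50 UMIs. The complement list holds C1qa, C1qb, C1qc and Ms4a7, which were counted as free RNA in these cells, and H2-Ab1 and H2-Aa led the cDC2-like cluster. The complement and MHC class II medians need therefore not be changes in T-cell-like cells. Neither list gave a value with members of at least 200 UMIs. With clusters matched, suppressive factors (0.040), alternative activation (0.22), complement (-0.28), dissociation (-0.05) and naive genes (-0.16) lay within the random range, MHC class II genes (-0.33) stayed below it, and cell cycle (0.51) and monocyte genes (0.31) lay above it. Without the Gzmm-led cluster the matched complement (-0.34) and naive lists (0.62) lay outside it and the monocyte list (0.015) within. Inflammatory activation was at -0.038 with a 500-UMI minimum. Cells of the unnamed cluster led by Rrm2 and Ube2c are in none of these values.

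The lowest genes in all T-cell-like cells were Ncmap (-2.89), Bnip3 (-2.85), Ramp1 (-2.39), Hspa1a (-2.24), Nt5e (-2.12), Maf (-1.96), Wls (-1.89), Itgae (-1.85), Il10, Bmyc (-1.82), Izumo1r (-1.78) and Ddit4 (-1.76). With clusters matched, Hspa1a was at -1.97, Bnip3 at -1.79, Ramp1 at -1.42 and Ncmap at -1.29. Nt5e was then at -0.75, Ddit4 at -0.57, Maf and Wls at -0.49, Bmyc at -0.39, Il10 at -0.35, Itgae at -0.26 and Izumo1r at -0.23. The highest were S100a8 (1 against 249 UMIs, interval 3.10 to 10.9, and 0 UMIs in both libraries after subtraction of free RNA), Gzma, Ly6c2 (2.91), Wdr95 (2.88), Gzmk, St3gal6 (2.37), Ifitm1 (2.36), Cd86 (2.13), Fam26f (1.94), Cd226 (1.88), Gramd3 (1.86) and Cd8b1 (1.71). With clusters matched, and so without the Gzmk-led cluster, S100a8 had an interval of 3.76 to 12.5 and Ifitm1 was at 2.27. Gzma was at 2.56 and Wdr95 at 1.52, but at 1.01 and 0.27 without the Gzmm-led cluster. St3gal6 turned to -0.10 (-0.85 to 0.69), and was at 0.42 without the Gzmm-led cluster. Gzmk (0.69, and 0.14 without it), Gramd3 (0.58, and 1.24), Ly6c2 (0.39, and 0.67), Cd86 (0.65), Cd226 (0.29), Cd8b1 (0.064) and Fam26f (0.037) were smaller as well.

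Regulatory T-cell-like cells formed a single cluster in both libraries, with 161 control and 292 anti-PD-1 cells. Hypoxia and glycolysis genes were lower in 20 of 20 measured members (median -0.74, random range -0.13 to 0.17), led by Bnip3 (269 and 63.8 CPM, log2 -2.08) and the glycolytic enzyme Eno1 (-1.50). Cell cycle genes were higher in 20 of 22 (median 0.94), with Birc5, a mitosis gene, at 3.15. Interferon genes (0.18), naive T-cell genes (0.46), monocyte genes (0.72), inflammatory activation (0.43) and neutrophil genes (1.39) were higher and inhibitory receptors (-0.24) lower. Against 8 lists here, 5 lay outside the random range in thinned cells and with equal weight per cell, and 3 with members of at least 200 UMIs. At that minimum the naive, monocyte, inflammatory and neutrophil lists gave no value. Inflammatory activation turned to -0.14 and -0.066 with UMI minimums of 500 and 1000 and to -0.17 with the highest doublet scores removed, and the neutrophil list, with 4 measured members, gave no value after subtraction of free RNA. The remaining named genes were Fam162a (-1.35) and H2-Ab1 (-1.56) on the low side and Cxcl10 (1.81), Hmgn1 (1.61) and S100a8 (1 against 79 UMIs, interval 3.02 to 10.9, and 0 UMIs in both after subtraction of free RNA) on the high side. H2-Ab1 was among the leading genes of the cDC2-like cluster, so its ratio need not be a change in regulatory T-cell-like cells.

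In NK-cell-like cells, cell cycle genes were higher in 21 of 22 members (median 0.87) and cytotoxic effector genes in 16 of 21 (median 0.35). The unnamed cluster led by Rrm2 and Ube2c, with Ncr1 at 44.0 CPM, is outside this class. The granzymes Gzmd (115 and 1047 UMIs, log2 2.53), Gzme (2.45), Gzmf (3.37) and Gzmg (1 against 239 UMIs, interval 4.76 to 12.6) were the 4 highest genes, whereas Gzmb was at 0.04 (-0.03 to 0.11). These 4 granzymes are among the leading genes of 1 of the 2 NK-cell-like clusters, which held 70 of 347 control and 186 of 534 anti-PD-1 cells of the class. With the clusters matched, the ratios of Gzmd, Gzme and Gzmf were 1.94, 1.86 and 2.79, and Gzmb was at 0.05. Interferon genes (22 of 32, median 0.32), MHC class I genes (0.35) and regulatory T-cell genes (0.38) were higher, and suppressive factors (-0.28) and dissociation genes (-0.08) lower. The hypoxia list lay within the random range (-0.08). With the NK-cell-like clusters matched, hypoxia (-0.15) and MHC class II genes (-0.50) lay below random lists, inflammatory activation (0.50), chemokines (0.43) and monocyte genes (0.37) above them, and regulatory T-cell (0.083) and dissociation genes (0.085) within. The lowest genes were Apoe (-1.42), Hspa1a (-1.20), H2-Q4 (-1.05) and H2-Aa (-0.98), which was at 0.97 after subtraction of free RNA. Apoe is a macrophage gene counted as free RNA in these cells, and H2-Aa was among the leading genes of the cDC2-like cluster. Neither these ratios nor the matched MHC class II median need therefore be changes in NK-cell-like cells.

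In cDC2-like cells, with 69 control and 82 anti-PD-1 cells, interferon response genes were higher in 32 of 34 members (median 0.59) and chemokines in 11 of 12 (median 1.06). Cxcl10 was at 92.3 and 875 CPM (log2 3.24, 2.80 to 3.72), Ccl5 at 3.39, Gzmb at 3.10, Ly6d at 3.15 and Cxcl9 at 1.69. Inflammatory activation (0.81), complement (1.04), monocyte (0.66), cytotoxic (0.67), suppressive (0.61) and MHC class I genes (0.35) were higher. Gzmb and the cytotoxic list belong to lymphocytes and the complement list to macrophages, and cells of mixed type remain in the data. Cell cycle (-0.65), hypoxia (-0.54), alternative activation (-0.45), inhibitory receptor (-0.40), dissociation (-0.38) and MHC class II genes (-0.25) were lower. Median depths were 7053 UMIs in control and 4861 in anti-PD-1. Against 14 lists here, 5 lay outside the random range in thinned cells and 9 with members of at least 200 UMIs. The suppressive, complement and inhibitory receptor lists gave no value in either. Alternative activation had 5 of 11 members higher and a mean of 0.18, and its median turned to 0.11 at 5% mitochondrial UMIs and 0.075 at resolution 2.0. The lowest genes were the heat-shock genes Hspb1 (72 against 0 UMIs, a log2 ratio of -4.36 or lower) and Hspa1a (-3.07), then Cd209e (-2.04) and Ear2 (-1.57).

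**Figure D3:**
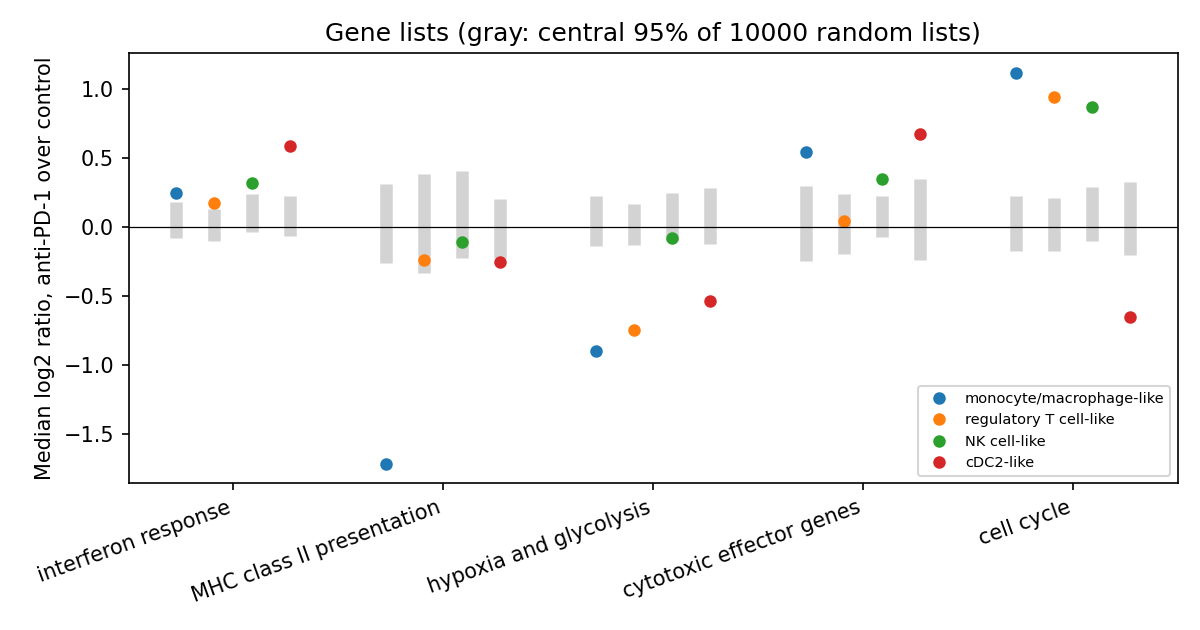
Median log2 ratio (anti-PD-1 over control) of 5 gene lists in 4 cell classes; gray bars span the central 95% of 10000 random lists matched on expression. The hypoxia list lies at -0.90, -0.74 and -0.54 in monocyte/macrophage-like, regulatory T-cell-like and cDC2-like cells, and within the gray bar in NK-cell-like cells. Cluster-matched, it lay below random lists at -0.18 in monocyte/macrophage-like cells (-0.020, within their range, without subcluster 4) and at -0.15 in NK-cell-like cells.

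The last comparison asked which genes went with Arg1 inside the monocyte/macrophage-like class of each library. At 2000 UMIs per cell, 148 control cells had an Arg1 UMI and 145 had none, and 101 and 370 in anti-PD-1, with 37 and 35 shallower cells left out. Hypoxia and glycolysis genes were higher in Arg1-positive cells of both libraries (19 of 20 members, median 1.24, in control and 17 of 19, median 1.34, in anti-PD-1), among them Hilpda (3.83 and 2.25) and Bnip3 (2.73 and 2.21). Suppressive factors (0.90 and 1.03), lipid and phagolysosomal genes (0.84 and 1.18), complement genes (1.10 and 1.90), alternative activation (1.04 and 1.06) and interferon genes (0.26 and 0.42) were also higher in both. The split sets the direction of Arg1, which is a member of the suppressive and alternative activation lists. Without it their medians were 0.82 and 1.01 for suppressive factors and 0.97 (5 of 9 higher, mean -0.04) and 0.70 (4 of 6) for alternative activation, still above random lists. Monocyte genes were lower (-1.19 and -1.84), as were naive T-cell genes (-1.35 and -1.03).

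Among genes with at least 50 UMIs in the higher cells of each library, which leaves out Bnip3, the 12 highest in both libraries were the secreted phosphoprotein Spp1 (log2 2.87 in control and 3.13 in anti-PD-1), Gatm (2.90 and 2.63), AA467197 (2.84 and 2.27), Hilpda, Rgs1 (2.23 and 2.70), Mt1 (2.43 and 1.99), Ms4a7 (1.95 and 3.05), Cxcl16 (1.92 and 2.32), Bcl2a1b (2.32 and 1.83), Hmox1 (2.29 and 1.80), Cd63 (1.68 and 2.33) and Mif (1.62 and 2.25). The 12 lowest were Ifitm6 (-3.70 and -4.62), Hp (-3.84 and -3.63), Gsr, Itga4, Tmem176b, Lsp1, Napsa, Adgre5, Gpcpd1, Rnase6, Nadk and Mcemp1. Within subcluster 3 of control, where 32 positive and 61 negative cells allowed a split, the hypoxia (0.85), lipid (0.58) and suppressive lists (0.70 with and 0.70 without Arg1) stayed above random lists, and monocyte (0.087) and complement genes (0.12) lay within the random range. Alternative activation, left with 3 measured members without Arg1, gave no value there. Ms4a7 and Rgs1 were at -0.069 in that subcluster and Adgre5 turned from -1.88 to 0.76. Over the whole class, MHC class II genes were at 0.30 and 1.04 and inflammatory activation at 0.29, within the random range, and 0.84, whereas within subcluster 3 of control MHC class II was at -0.000185, within the random range, and inflammatory activation at 0.78, above it. Over the class the arginine list was at 0.12 and 0.00 (-0.14 and -0.027 without Arg1), within it in both.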

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

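Shared UMI minimums of 1000 and above, free-RNA subtraction and thinning were planned before the data were examined, but every test of an explanation in this part was set out after the result it bears on had been seen, and the 500-UMI minimum, highest doublet scores, cluster matching and leaving out subclusters were added then as well. The list differences between groups were not tested, as each group is 1 library.

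In Arg1-positive over Arg1-negative cells, 3 lists lay outside random lists in opposite directions in the 2 libraries. Chemokines were at -0.34 in control and 1.34 in anti-PD-1, cell cycle genes at 0.56 and -0.65, and neutrophil genes at 1.16 and -1.11. The Arg1-negative cells differed between the libraries. Subcluster 6, led by S100a8 and S100a9, held 64 anti-PD-1 cells without an Arg1 UMI and no control cell. The difference in neutrophil genes need therefore not lie in the Arg1-positive cells. In control, the chemokine median changed sign with all UMIs in the split (0.70), with a 500-UMI minimum (0.038) and with the highest doublet scores removed (0.019). With the split made within subclusters, control chemokines (-0.023) and cell cycle genes (-0.23) lay within the random range and neutrophil genes gave no value.

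Between cell classes, the cell cycle list moved apart in anti-PD-1 over control, at 1.12 in monocyte/macrophage-like, 0.94 in regulatory T-cell-like and 0.87 in NK-cell-like cells but -0.65 in cDC2-like cells. The unnamed cluster 14, led by proliferation genes, held 13 control and 113 anti-PD-1 cells and enters none of these medians. Its levels were 192 CPM for Mki67, 317 for Cd3e, 448 for Cd8a, 44.0 for Ncr1 and 1.91 for Foxp3. The lymphocyte medians are thus those of cells left outside it. Suppressive factors were at -0.60 in monocyte/macrophage-like, -0.28 in NK-cell-like and 0.61 in cDC2-like cells. Chemokines were at -0.52 in monocyte/macrophage-like and 1.06 in cDC2-like cells, and complement genes at -1.11 and 1.04. With subclusters weighted alike, the monocyte/macrophage-like suppressive (-0.04) and chemokine medians (0.093) lay within the random range, and complement (-0.25) and cell cycle genes (0.87) outside it, while cell cycle was at -0.031 at resolution 2.0.

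Barcodes between 500 UMIs and each library's minimum enter only the alternatives with lower UMI minimums, and 231 of 833 such anti-PD-1 cells were neutrophil-like against 35 of 93 in control.

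The higher CD8 T-cell-like share in anti-PD-1 was weighed first. With the same UMI minimum in both libraries the lowest share ratio was 7.58 (5.41 to 10.6), which argues against unequal minimums. Only 0.395% of anti-PD-1 monocyte/macrophage-like cells carried Cd8 and Cd3 UMIs, which argues against free T-cell RNA. The ratio of CD8-like to CD4-like cells was 7.68 times (4.46 to 13.2) that of control, but a loss of other classes that took CD4-like cells too would give the same, so such a loss stays open. The treatment itself, and any difference between animals or sorts, stay open and untested, since each group is 1 library.

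The lower Arg1 level of monocyte/macrophage-like cells was weighed next. The log2 ratio was -1.68 after free-RNA subtraction and -1.34 without subclusters 6 and 8, so neither accounts for it alone. The cluster-matched ratio, which also leaves out subclusters 6 and 8, was -0.51 (-0.58 to -0.44), -0.17 (-0.25 to -0.10) without subcluster 4 and its 12 control cells and -0.69 (-0.78 to -0.60) without subcluster 7 and its 11 anti-PD-1 cells. Its intervals treat averaged levels as counts and are too narrow for these few cells. Set beside -1.34, a shift between the matched subclusters may account for much of the difference. Whether it accounts for all of it stays open, as what is left moves with these thinly filled subclusters. The Arg1 ratios of subclusters 1, 4 and 7 also changed sign across settings. For 1 and 4 this was only where subclusters were found anew and can hold other cells. The ratio of subcluster 3 was -2.56 and at its smallest -1.99, with 34 and 10 Arg1-positive cells. An effect of the treatment was not tested and stays open too.

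The lower hypoxia list in regulatory T-cell-like cells was weighed last. Its median was -0.74 after free-RNA subtraction and -0.68 in cells thinned to 1 depth, both below random lists. The dissociation list was at 0.06 in the same cells, within its random range of -0.15 to 0.19. A list median within that range cannot exclude a difference in handling between the libraries. The same list lay below random lists in monocyte/macrophage-like, cDC2-like and, without cluster matching, NK-cell-like cells. Stress during dissociation therefore stays open. Tumour size, oxygen supply and the treatment were not tested and stay open.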

How the results depend on the processing

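The direction of the CD8 T-cell-like, all T-cell-like, NK-cell-like, monocyte/macrophage-like, cDC2-like and neutrophil-like share ratios held in every alternative that gave a value, as did the lower class-wide Arg1 level in anti-PD-1 and the lower hypoxia list in regulatory T-cell-like cells. The size of the class-wide Arg1 difference, and the Arg1 ratios of subclusters 1, 4 and 7, did not hold. For subclusters 1 and 4 the sign changed only where subclusters were found anew, with numbers carried over from the main ones by shared cells. Among values that answer a comparison, 298 alternative values counted as unchanged, 57 as moved and 10 changed sign. Among single genes and lists these were 3821, 539 and 37. Unchanged means within the counting interval of the main value for levels, shares and ratios. For list medians it means within a span as wide as the random range, centred on the main median. Counts of lists were allowed to differ by a fixed factor instead. Sign changes are counted only for values whose main interval excluded no change, or for lists outside random lists, which leaves out those of subcluster 7. Unless the setting itself gives fewer genes or cells, the cause was not tested. The alternatives with a 500-UMI minimum, highest Scrublet scores removed, cluster matching (also without single clusters), without subclusters 6 and 8, list members at 50 UMIs and Arg1 left out of the lists (also within subclusters) were chosen after seeing the data. The median log2 ratio over genes of NK-cell-like cells was 0.14, and median-ratio scaling, which sets it to 0, turned no called direction. Alternatives gave no value where a class lost its name, a gene fell to the floor or a list kept too few members, as for S100a8 and neutrophil genes in T-cell-like cells after free-RNA subtraction, and the Arg1 split within subclusters gave none in anti-PD-1. Below, subcluster shares are ratios of shares of the class, Arg1 ratios are log2, and the main value follows in brackets.

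With a 500-UMI minimum in both libraries the share ratio was 14.1 (9.59) for CD8 T-cell-like and 2.86 (5.77) for neutrophil-like cells, and 0.51, 2.29 and 0.568 (0.754, 3.86 and 0.163) for subclusters 1, 2 and 7. Arg1 ratios were -0.38, -2.11 and -0.85 (0.40, -2.56 and -4.84) in subclusters 1, 3 and 4, and 21.7% (17.0%) of anti-PD-1 cells were Arg1-positive. Inflammatory activation was at -0.038 (0.35) in all T-cell-like and -0.14 (0.43) in regulatory T-cell-like cells, and chemokines at 0.038 (-0.34) in Arg1-positive control cells. With a 1000-UMI minimum the shares of subclusters 1 and 4 were 0.551 and 1.71 (0.754 and 4.08), their Arg1 ratios -0.21 and 3.47 (0.40 and -4.84), 20.7% (17.0%) of anti-PD-1 cells were Arg1-positive, and inflammatory activation in regulatory T-cell-like cells was at -0.066 (0.43). With the higher minimum in both libraries the neutrophil-like share ratio was 19.8 (5.77), the shares of subclusters 1 and 4 were 0.55 and 20.4 (0.754 and 4.08), and Arg1 ratios in subclusters 1, 3 and 4 were -0.17, -2.19 and -1.56 (0.40, -2.56 and -4.84).

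At most 5% mitochondrial UMIs gave an Arg1 level of 781 CPM (749) in anti-PD-1, Arg1 ratios of -1.58 (-1.68) in the class and 0.016 (0.40) in subcluster 1, a share of subcluster 1 of 0.593 (0.754), and alternative activation in cDC2-like cells at 0.11 (-0.45). At most 20% gave an Arg1 ratio of -0.52 (-0.10) in subcluster 7. No doublet removal gave a share of 1.43 (4.08) and an Arg1 ratio of 0.80 (-4.84) in subcluster 4. Removing the highest Scrublet scores gave 801 CPM (749) in anti-PD-1, Arg1 ratios of -1.60 (-1.68) in the class and -0.27 (0.40) in subcluster 1, a share of subcluster 2 of 6.11 (3.86), inflammatory activation in regulatory T-cell-like cells at -0.17 (0.43) and chemokines in Arg1-positive control cells at 0.019 (-0.34).

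Resolution 2.0 gave a monocyte/macrophage-like share ratio of 0.366 (0.601), Arg1 levels of 2299 (2405) CPM in control and 1634 (749) in anti-PD-1, Arg1 ratios of -0.49 (-1.68) in the class and -0.10 (0.40) in subcluster 1, and 30.1% (17.0%) Arg1-positive anti-PD-1 cells. Shares of subclusters 1, 3 and 5 were 1.12, 0.549 and 1.91 (0.754, 0.275 and 0.531). Cell cycle genes of the class were at -0.031 (1.12), S100a8 at -0.265 (4.84), S100a9 at -1.375 (2.75), and alternative activation in cDC2-like cells at 0.075 (-0.45). At that resolution the class held 263 control and 246 anti-PD-1 cells in place of 330 and 506. Resolution 0.5 gave naive T-cell genes at -0.0012 (0.39) in all T-cell-like cells. Clustering with Arg1 and the left-out lists gave shares of 0.56 and 2.46 (0.754 and 3.86) for subclusters 1 and 2 and Arg1 ratios of -0.11, -2.13 and -3.32 (0.40, -2.56 and -4.84) for subclusters 1, 3 and 4.

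Equal weight per cell gave Arg1 levels of 2112 and 797 CPM (2405 and 749), Arg1 ratios of -1.41 (-1.68) in the class and 0.091 (-0.10) in subcluster 7, naive T-cell genes at -0.030 (0.39) in all T-cell-like cells, and 5 (8) lists outside the random range in regulatory T-cell-like cells. Thinning to 1000 UMIs gave 2136 and 796 CPM, Arg1 ratios of -1.42 (-1.68) in the class and 0.52, -1.99, -4.31 and 0.069 (0.40, -2.56, -4.84 and -0.10) in subclusters 1, 3, 4 and 7, and Spp1 at -0.094 (0.36). It left fewer measured members, and 6 (11) lists were outside the random range in all T-cell-like, 4 (7) in NK-cell-like, 5 (8) in regulatory T-cell-like and 5 (14) in cDC2-like cells. A minimum of 200 UMIs left 3 (8) and 9 (14) such lists in regulatory T-cell-like and cDC2-like cells. Of the genes named by size, a 20-UMI minimum shared 24 of 24 in monocyte/macrophage-like, 21 of 24 in all T-cell-like, 8 of 8 in NK-cell-like, 3 of 8 in regulatory T-cell-like and 3 of 8 in cDC2-like cells, and a 200-UMI minimum 15, 16, 4, 1 and 2. Free-RNA subtraction turned H2-Aa in NK-cell-like cells to 0.97 (-0.98).

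Cluster matching turned chemokines to 0.093 (-0.52) and lipid genes to 0.20 (-0.43) in monocyte/macrophage-like cells, and dissociation genes to 0.085 (-0.08) in NK-cell-like cells. In all T-cell-like cells it turned suppressive factors to 0.040 (-0.52), alternative activation to 0.22 (-0.74), naive T-cell genes to -0.16 (0.39), Gzmb to 0.073 (-0.51) and St3gal6 to -0.10 (2.37), with 7 (11) lists outside the random range. With subcluster 4 left out of the matching, chemokines were at 0.16 (-0.52), lipid genes at 0.18 (-0.43), monocyte genes at -0.11 (0.82) and Cdc42ep2 at -0.0080 (2.23); with subcluster 7 left out, chemokines at 0.19 and lipid genes at 0.22; and with the Gzmm-led cluster 8 left out, dissociation genes in all T-cell-like cells at 0.057 (-0.51). Without subclusters 6 and 8 the anti-PD-1 Arg1 level was 937 CPM (749) and the class ratio -1.34 (-1.68). The Arg1 split within subclusters, on fewer cells, left 6 (14) lists in control outside the random range and turned MHC class II genes to -0.000185 (0.30), monocyte genes to 0.087 (-1.19), cell cycle genes to -0.23 (0.56), Adgre5 to 0.76 (-1.88), Ms4a7 to -0.069 (1.95) and Rgs1 to -0.069 (2.23); with Arg1 also left out of the lists, 5 (14) lay outside it. Using all UMIs in the split turned chemokines in control to 0.70 (-0.34).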

Other observations

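The clusters that stayed unnamed held lymphocyte genes. Cluster 7, led by Klra1, Il22, Dapl1 and Tcf7, held 96 control and 146 anti-PD-1 cells. Cluster 14, led by the proliferation genes Rrm2, Ube2c, Top2a and Birc5, held 13 control and 113 anti-PD-1 cells. Cluster 14 formed although the cell cycle list was left out of the clustering. Neither cluster counts among the T-cell-like shares or enters the ratios of the T- and NK-cell-like classes.

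The neutrophil transcript S100a8 was also more frequent in anti-PD-1 cells that should lack it, with 249 UMIs against 1 in all T-cell-like and 79 against 1 in regulatory T-cell-like cells, in a library that held 162 neutrophil-like cells against 11. After subtraction of free RNA, 0 UMIs were left in both classes and libraries.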
